A study of Mus musculus with 4 samples.

How the data were processed

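RNA from sorted mouse bone marrow cells was measured on 4 Affymetrix Mouse Gene 2.0 ST arrays, a platform that probes transcripts along their whole length. There was 1 array for each of 4 genotypes: wild type (WT), Fancd2 knockout (Fancd2KO), Foxo3a knockout (Foxo3aKO) and the double knockout (DKO). Per the labels, the mice were 2 months old, mononuclear marrow cells were taken from a Ficoll gradient, and the sorted cells were lineage-negative, c-Kit-positive, Sca-1-positive and CD34-negative, a gate that holds long-term haematopoietic stem cells. The labels call these cells SLAM cells but list neither CD150 nor CD48, the antigens that usually define that name. Lineage antibodies, the number of mice or cells per array, the sex of the mice and the knockout alleles were not given in the sources used here.

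The deposited table held 41345 probe sets, with 1 column per array, and all 4 columns were used. Its values were log2 expression values made by the authors, per the range of the deposited values. Processing used Affymetrix Expression Console, per the submitters' processing notes. The version, the summarisation and normalisation methods and any filter were not given in the sources used here. The sorted values of the arrays lay within 0.0889 log2 of their common mean at every rank, so the arrays had nearly the same distribution as deposited. The between-array normalisation was therefore left as deposited, and other normalisations were tried as alternatives.

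Probe sets were named from the platform annotation. Of the 41345 probe sets, 23521 had 1 gene symbol, 1814 had several and 16010 had no listed gene. The Entrez identifiers of 23328 of the probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols differed from it. That table served only for names, and no coordinates are given because the build behind the probe sets was not given in the sources used here. Only probe sets with 1 symbol were used, and the probe set with the highest mean over the 4 arrays stood for its gene, which gave 22180 genes. A gene entered the comparisons when its highest value on the 4 arrays was at or above the median of all gene values, 5.51 log2, which 12041 genes reached. The 190 control probe sets were used only to check the arrays. Members of gene families with near-identical copies can share probes, so their single values are uncertain.

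No genotype had replicates. No p-value, standard error or test between genotypes is given for that reason, and each difference describes a pair of arrays with no replicate check. The number of arrays limits the precision. Values were subtracted on the log2 scale for each knockout minus WT, for DKO minus each of the other knockouts, and for DKO minus the additive expectation, which is Fancd2KO plus Foxo3aKO minus WT. Genes at least 2-fold higher or lower, a log2 difference of 1 in size, were counted. The technical error that single arrays allow was taken from 618 genes with 2 probe sets, as the disagreement of the 2 probe sets about the same difference.

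For 20 pathway or process lists and 10 marker lists, the median difference of a list was placed among the medians of 10000 random lists of the same size drawn from the same 20 bins of mean expression. A list was said to stand apart below the 1st or above the 99th percentile. Pathway lists used the floor on dim genes, marker lists did not, and a list with fewer than 5 measured genes received no percentile. These percentiles describe the arrays at hand. Genes of a list are not independent, so any pair of samples can differ in more lists than the 2% that independent genes would give. Comparisons that share an array share its error. Their correlation and overlap across genes were therefore set beside 200 simulated sets of 4 unchanged arrays and beside the overlap of independent lists. The simulated arrays drew each gene around its mean with its SD over the 4 arrays, which holds any real difference between genotypes as well as error. Genes were drawn independently of each other, so the simulated ranges are too narrow for genes that vary together.

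The lists, the thresholds and the rule for genes named in the text were fixed before the data were examined. The rule names Fancd2 and Foxo3, the 12 genes with the largest difference in each direction for each knockout against WT, the 6 largest for the other comparisons, up to 4 members of each list that stood apart and up to 3 markers per marker list. Predicted genes, clones, pseudogenes, small RNAs, chemosensory receptors and antigen receptor segments were counted and not named. The pseudogene suffix was added to that rule once the symbols were known. Of the 12041 genes, 10856 could be named and 1185 could not. After the data were seen, 8 further lists were added: neuronal, astrocyte, myelin and oligodendrocyte, imprinted, non-classical monocyte, classical monocyte, rapid response and heat shock genes.

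Alternatives were quantile normalisation, centring of each array on its median, cyclic loess, no floor, a floor on the mean of the 4 arrays, a floor at the 75th percentile, the mean of all probe sets of a gene, thresholds of 1.5-fold and 3-fold, and counts of genes that could be named. Another 4 alternatives were added after the data were seen: lists without immediate early and rapid response genes, counts without marker, immediate early and added-list genes, marker lists with the floor, and differences of named genes with every signal under the floor raised to it. The last shows how far a difference rests on dim signals. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.

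The counting and list steps were tested on simulated data for the comparison of Fancd2KO with WT over 12041 genes, with the same spread per gene. Of genes raised 2-fold, 63% were counted as at least 2-fold higher. The share was 96% for genes raised 4-fold and 1.85% for unchanged genes. Of 40 lists of 30 genes shifted by 0.3 log2, 40 stood apart, and 0 of 40 unshifted lists did.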

Results

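The data describe gene expression in bone marrow cells sorted with a gate for haematopoietic stem cells, from mice labelled as lacking Fancd2, Foxo3a or both. Fancd2 is a central protein of the Fanconi anaemia pathway, which repairs DNA interstrand crosslinks. Foxo3a, encoded by Foxo3, is a forkhead transcription factor known for roles in stress resistance and stem cell quiescence. The design has 2 genes, each present or absent, with 1 array per combination, and so asks how each loss alone and both losses together go with expression. With 1 array per genotype, no difference below has a replicate check.

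The 4 arrays were close in overall signal. Array medians over 41345 probe sets were 5.28 for WT, 5.27 for Fancd2KO, 5.34 for Foxo3aKO and 5.31 log2 for DKO. The spiked hybridisation controls stood in their designed order on every array, from bioB at 10.03 to 10.14 to cre at 13.80 to 13.91. Background probe sets rich in G and C had medians of 6.59 for WT, 6.51 for Fancd2KO, 6.06 for Foxo3aKO and 6.70 for DKO. Those poor in G and C had medians of 2.03, 2.12, 2.01 and 2.09 on the same arrays. Signals near the upper levels carry little information where probes are rich in G and C, which was not known for single genes. The G and C rich background was lowest on the Foxo3aKO array, and no normalisation tried took G and C content into account. How far differences with that array carry this offset was not tested. Pearson correlations between pairs of arrays over all probe sets ran from 0.965 to 0.969. For genes with 2 probe sets, the SD of the disagreement between both was 0.48 log2 for Fancd2KO minus WT, 0.47 for Foxo3aKO minus WT and 0.49 for DKO minus WT. The disagreement was under 0.94, 0.93 and 0.92 in 95% of these genes, close to the 2-fold threshold.

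The targeted genes were examined first. Fancd2 (probe set 17461739) stood at 6.56 log2 in WT, 6.08 in Fancd2KO, 6.67 in Foxo3aKO and 5.84 in DKO. It was lower than in WT by a log2 difference of -0.48 in the Fancd2KO array and -0.72 in the DKO array, within the disagreement of probe sets. Foxo3 (probe set 17240529) stood at 6.62, 6.72, 6.64 and 6.51 on the same arrays. The arrays labelled Foxo3a knockout and double knockout thus showed no lower Foxo3 signal, with differences of 0.02 and -0.10 from WT. The labels name no deleted exons and the exons under this probe set were not known, so this signal does not check the labels. Fancd2 and Foxo3 signals also lay near the G and C rich background, whose medians ran from 6.06 to 6.70. Directions assigned to Foxo3a loss rest on the labels alone.

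In the array labelled Fancd2 knockout, 202 of 12041 genes were at least 2-fold higher than in WT and 163 were at least 2-fold lower. Simulated unchanged arrays gave 203.5 higher genes on average (167 to 237) and 203.5 lower genes (169 to 242). They carry each gene's own spread over the 4 arrays, which holds real differences too. The counts alone therefore neither show nor exclude an effect. At a 1.5-fold threshold the balance turned, to 664 higher and 757 lower. Stimulus-induced immediate early genes were higher together. The list had 33 measured members, of which 32 were higher and 16 at least 2-fold higher, with a median of 0.91 log2, above all 10000 random lists. Its leading members were the nuclear receptors Nr4a2 (3.30), Nr4a1 (2.81) and Nr4a3 (2.22) and the cytokine signalling inhibitor Socs3 (2.88), which was 1.75 higher with the mean of its probe sets. Cdkn1a, which encodes the cell cycle inhibitor p21 and is on the FOXO and p53 lists, was higher by 3.01. Transcripts best known from neural tissue headed the higher genes: Cdr1 (4.69), Pcp4 (3.72), the synaptic fusion gene Snap25 (3.46), Sparcl1 (3.01), the prohormone-processing gene Cpe (2.82) and the calcium sensor Vsnl1 (2.56). A list of neuronal genes chosen after these values were seen had a median of 0.82 over 25 measured genes, of which 7 were at least 2-fold higher. The fatty acid carrier Fabp4 (2.31) and Rsph3a (2.28) were also high, and Rsph3a was 0.95 higher with the mean of its probe sets. Several of these genes lay under the floor in WT, so the sizes are not exact. With signals under the floor raised to it, a choice made after the data were seen, the differences were 3.16 for Pcp4, 2.18 for Cdr1, 1.92 for Snap25, 1.78 for Cpe, 1.77 for Sparcl1 and 0.87 for Vsnl1, whose 6.38 log2 in Fancd2KO lay below the G and C rich background of 6.51.

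Signalling lists also stood apart in the Fancd2KO array. Of 37 measured genes of WNT, Notch and TGF-beta signalling, 7 were at least 2-fold higher and 0 lower (list median 0.23, percentile 99.99). Among them were the TGF-beta feedback genes Skil (1.82) and Smad7 (1.35), the Notch target Hes1 (1.81) and the Notch ligand Jag1 (1.23, or 0.45 with dim signals raised to the floor). The TNF and NF-kB list had a median of 0.17 (percentile 99.8), and 5 of 33 members were at least 2-fold higher, among them Ccl2 (1.81), Ier3 (1.56), Ptgs2 (1.48) and Junb (1.22). Ier3 and Junb are also on the immediate early list, so these lists are not independent. Type I interferon response genes were lower, with 34 of 41 members below WT and a median of -0.22, below all random lists. Irgm2 (-1.42) was the member at least 2-fold lower, and Rtp4 (-0.84), Usp18 (-0.71) and the regulator Irf7 (-0.63) followed.

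Genes of multipotent progenitors, the stage after the stem cell, had a median of -0.22 (percentile 0.09) in the Fancd2KO array, with 14 of 24 lower and 10 higher. The cytokine receptor Flt3 (-1.63) and the lymphoid enzyme Dntt (-1.30) were at least 2-fold lower, while Satb1 differed by -0.88 and Cd48 by -0.66. FOXO target genes had a median of -0.17 (percentile 0.28), with 24 of 37 lower. Txnip (-1.02) was the member at least 2-fold lower, followed by Bcl6 (-0.76), Fbxo32 (-0.69) and Sesn3 (-0.63), while 4 members were at least 2-fold higher, Cdkn1a among them. DNA replication genes had a median of 0.12 (percentile 99.2), and 0 of 36 were 2-fold apart: Orc1 differed by 0.82, Fen1 by 0.54, Prim1 by 0.33 and Mcm5 by 0.32. Respiratory chain genes had a median of 0.09 (percentile 99.4), with 0 of 53 at 2-fold and Atp5j2 (0.89), Ndufa9 (0.79), Atp5d (0.49) and Cyc1 (0.36) in front. Both of these calls ended under quantile normalisation, at percentiles 98.95 and 98.7. Of 45 stem cell genes (median 0.10, percentile 98.8), 3 were at least 2-fold higher. They were named after their values were seen: Socs2 (1.87), Slamf1 (1.11), which encodes CD150, and Vwf (1.08).

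Markers of other blood cells differed beside the genes above. In the Fancd2KO array all 19 neutrophil markers were lower than in WT (median -0.42), led by Ly6g (-1.35), Retnlg (-0.92) and Mmp9 (-0.87). Of 15 erythroid markers, 14 were lower (median -0.45), led by Car1 (-1.42), Ermap (-0.85) and Rhd (-0.78). Mast cell, basophil and eosinophil markers had a median of -0.74, with 6 of 18 at least 2-fold lower, among them the eosinophil granule genes Epx (-2.71), Prg3 (-2.04) and Prg2 (-1.47). All 3 medians lay below those of all random lists. Endothelial and stromal markers were higher (median 0.35, above all random lists), led by Sparc (1.32), Vwf (1.08) and Kdr (0.95). This list was dim, with median levels of 5.07 log2 in WT and 5.47 in Fancd2KO, and with dim signals raised to the floor Sparc differed by 0.98 and Kdr not at all. Inside the band were the lists of B cells (-0.13, percentile 11.4; Rag2 -1.31), T and NK cells (0.05, percentile 65.5; Cd3e 1.06, Gzmb -1.02), monocytes (-0.16, percentile 2.08; Adgre1 -1.17, Spic -1.02) and dendritic cells (-0.13, percentile 8.91). Rag2 and Gzmb lay under the floor on all 4 arrays, and Cd3e differed by 0.31 with dim signals raised to it. The largest lower difference was that of the platelet chemokine Ppbp (-3.11), on a megakaryocyte list whose median was -0.02 (percentile 48.7) and whose members Selp and Clec1b, the latter under the floor on all 4 arrays, differed by 1.55 and -1.15. The eosinophil ribonuclease Ear6 (-2.37), Alox15 (-2.34), Rnase12 (-2.34) and the chemokine Ccl6 (-2.01) were also among the 12 largest lower differences. So were Srsy (-2.49), Srsx (-2.17), Tdpoz2 (-2.21) and the zinc finger genes Zfp972 (-2.32) and Zfp108 (-2.18), which belong to families with similar copies. With dim signals raised to the floor, Srsx differed by -0.98, Zfp972 by -1.40 and Tdpoz2 by -1.46.

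**Figure D1:**
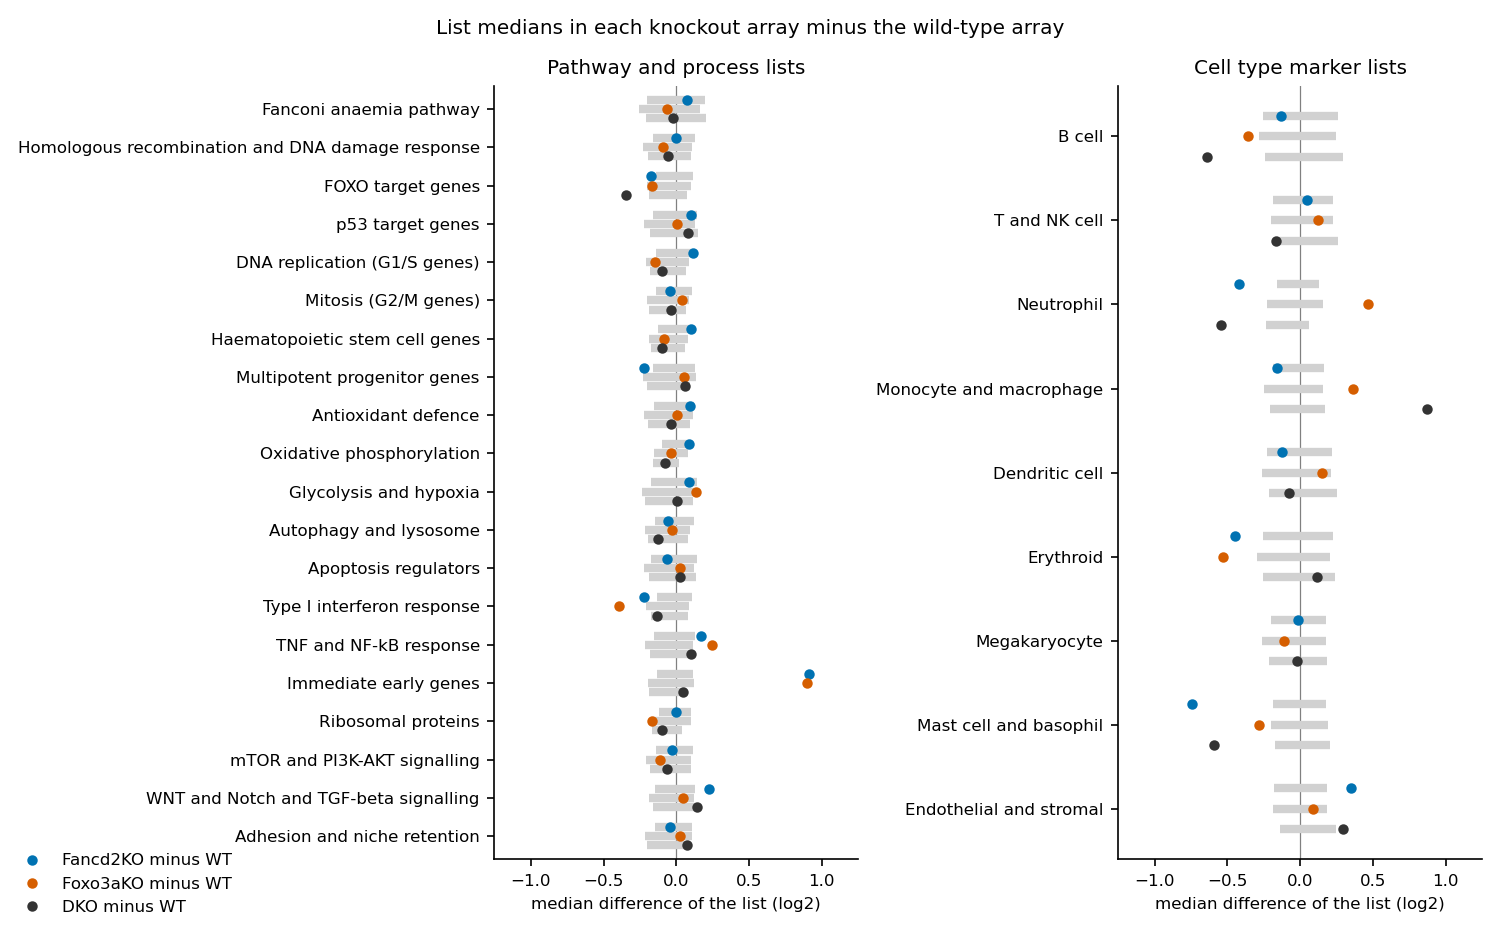
The median log2 difference of each list (points, x axis) is shown for Fancd2KO, Foxo3aKO and DKO minus WT, with 1 array per genotype, for pathway lists on the left and marker lists on the right. Grey bars span the 1st to the 99th percentile of random lists, and the immediate early list lies at 0.91 and 0.90 in the Fancd2KO and Foxo3aKO arrays but at 0.04 in the DKO array.

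In the array labelled Foxo3a knockout, 218 of 12041 genes were at least 2-fold higher than in WT and 156 were at least 2-fold lower. The balance turned with each array centred on its median, to 185 and 211, and at a 1.5-fold threshold, to 705 and 918. Immediate early genes were again higher, with a median of 0.90, above all random lists, and 14 of 33 members at least 2-fold higher. They were led by Nr4a2 (2.69), Atf3 (2.22), the heat shock gene Hspa1b (2.02) and Nr4a1 (1.85). The TNF and NF-kB list had a median of 0.25, above all random lists, with 6 of 33 members at least 2-fold higher, among them the monocyte chemokine Ccl2 (2.96), Ptgs2 (2.01) and Tnf (1.46). The inflammatory genes Il1r2 (3.16), a decoy receptor for interleukin 1, and Nlrp3 (2.26), an inflammasome sensor, were also high. Cdr1 (3.70) and Pcp4 (3.14) were higher here as in the Fancd2KO array, by 1.19 and 2.58 with dim signals raised to the floor, and the neuronal list had a median of 0.30, with 3 of 25 members at least 2-fold higher. The remaining genes among the 12 largest were Gdpd3 (2.47), the guidance ligand Slit2 (2.38), the matrix gene Thbs1 (2.36), the neutrophil granule gene Olfm4 (2.26) and Cd3d (2.24), a subunit of the T cell receptor complex.

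Type I interferon response genes were lower in the Foxo3aKO array. Of 41 members 37 were below WT and 4 at least 2-fold lower, with a median of -0.39, below all random lists. These 4 were the ubiquitin-like modifier Isg15 (-1.24), Rtp4 (-1.19), Usp18 (-1.19) and Lgals3bp (-1.01). FOXO target genes had a median of -0.17 that lay inside the band (percentile 3.91). Without Klf2, Klf4 and Klf6, which are also on the immediate early list, a choice made after seeing the data, the median was -0.34, below all random lists. Klf2 (1.07) and Klf6 (1.20) were at least 2-fold higher here, so leaving them out could only lower the median. The glycolysis and hypoxia list stood at 0.13 (percentile 99.3), with 0 of 26 at 2-fold and Ndrg1 (0.53), Vegfa (0.48), Hif1a (0.48) and Slc2a3 (0.46) in front. That call ended with no floor, at percentile 98.4, and with the mean of all probe sets, at 93.85 with a median of 0.07. The largest lower differences were Ppbp (-3.29), Rsl1 (-2.59), Dntt (-2.17), the histone gene H1f1 (-2.02), the melanocortin receptor Mc5r (-1.97), Epx (-1.81), Tmem143 (-1.77), the telomerase RNA Terc (-1.70), the macrophage factor Spic (-1.65), Flt3 (-1.60), the antiviral Apobec3 (-1.59) and the histone gene H2ac15 (-1.56). Rsl1 and the histone genes belong to families with similar copies. Rsl1 differed by -0.85 and Tmem143 by -0.24 with dim signals raised to the floor, both under 2-fold.

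Myeloid markers were higher in the Foxo3aKO array, beside the inflammatory genes. Of 19 neutrophil markers, 18 were higher (median 0.46), led by Ifitm6 (1.14), Mmp8 (1.01) and Anxa1 (0.91). Monocyte and macrophage markers had a median of 0.37, led by F13a1 (1.17) and Ly86 (1.15), with Spic against this direction. Both medians lay above all random lists. Erythroid markers were lower, with 14 of 15 below WT (median -0.53, below all random lists), led by Car1 (-1.48), Ermap (-1.06) and Hemgn (-1.02). B cell markers had a median of -0.36 (percentile 0.19), led by Vpreb3 (-0.99), Ly6d (-0.91) and Rag2 (-0.86). The list of mast cells, basophils and eosinophils had a median of -0.28 (percentile 0.06), and its members went both ways. The eosinophil genes Epx and Prg3 (-1.15) and the dim mast cell gene Mcpt4 (-1.42) were lower, while the basophil and mast cell genes Fcer1a (1.07), Mcpt8 (0.85), Hdc (0.62) and Prss34 (0.43), named after their values were seen, were higher. Other marker lists stayed inside the band, among them T and NK cells (median 0.12, percentile 87.4), with Cd3g at 1.20 and Ccl5 at 0.88, dendritic cells (0.15, percentile 95.8, or 99.3 with the floor), with Siglech at 1.31 and Irf8 at 1.25, and endothelial and stromal cells (0.09, percentile 86.0), with Pdgfrb at -0.98 and Bglap at -0.92. Megakaryocyte markers also did so (-0.11, percentile 22.9), with Ppbp at -3.29, Thbs1 at 2.36 and Clec1b at -1.18. With the floor, the endothelial and stromal median changed sign, to -0.24 (percentile 5.265), as did the megakaryocyte median, to 0.03 (percentile 83.13). Of the genes in this paragraph, Cd3g, Bglap, Clec1b, Rag2 and Mcpt4 lay under the floor on all 4 arrays.

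In the DKO array, 165 of 12041 genes were at least 2-fold higher than in WT and 207 were at least 2-fold lower, a balance that turned at a 3-fold threshold, to 57 and 50. Genes of monocytes and macrophages headed the higher genes: the Fc receptor Fcgr4 (4.08), the C-type lectin receptors Clec4a3 (4.01), Clec4a1 (3.67) and Clec4b1 (3.51), the activating receptor Cd300e (3.65) and Sirpb1a (2.67). Other genes among the 12 largest were the fatty acid carrier Fabp4 (4.06), the lipase Lipg (3.53), the nuclear receptor Pparg (3.33), Fcrl5 (3.15), the survival gene Bcl2a1a (3.12) and Ace (2.73), which encodes angiotensin-converting enzyme. With dim signals raised to the floor, Fabp4 was higher by 3.71, Bcl2a1a by 2.54, Pparg by 2.32, Ace and Lipg by 2.31, Fcrl5 by 1.94 and Clec4b1 by only 0.77. Monocyte and macrophage markers had a median of 0.87, above all random lists, with 9 of 22 at least 2-fold higher, among them Csf1r (1.93), the receptor for macrophage colony-stimulating factor, and Fcgr1 (1.82, or 1.07 with dim signals raised to the floor). The Clec4a, Sirpb1 and Bcl2a1 genes have close copies. A list of non-classical monocyte genes chosen after these values were seen had a median of 1.06 over 29 genes, of which 16 were at least 2-fold higher.

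FOXO target genes were lower in the DKO array. Of 37 members, 28 were below WT, with a median of -0.34, below all random lists. The interleukin 7 receptor gene Il7r (-1.31) and the cell cycle inhibitor Cdkn1b (-1.01) were at least 2-fold lower, followed by Sesn3 (-0.96) and Trp53inp1 (-0.95), while Il7r differed by -0.69 with dim signals raised to the floor. Il7r is also a progenitor gene and Trp53inp1 also a p53 target. Immediate early genes differed little from WT, with a median of 0.04 (percentile 97.0), and 2 of 33 were at least 2-fold higher. The TNF and NF-kB list lay at 0.10 (percentile 98.4) and the interferon list at -0.13 (percentile 6.69). With quantile normalisation, cyclic loess and the mean of all probe sets the TNF and NF-kB list stood apart, at percentiles 99.215, 99.51 and 99.01. Signalling genes of the WNT, Notch and TGF-beta list stood at 0.14 (percentile 99.2), with 0 of 37 at 2-fold and Dtx4 (0.84), Id3 (0.75), Hes1 (0.68) and Id2 (0.58) in front. Raised to the floor, dim signals left 0.42 for Dtx4 and no difference for Id3. Adhesion genes had a median of 0.07 (percentile 99.2), led by the leukocyte integrin Itgal (1.05), Vcam1 (0.96), Itga4 (0.41) and Itgb2 (0.37). Under quantile normalisation both calls ended, at percentiles 98.1 and 98.4. With the mean of all probe sets the adhesion median was 0.001, at percentile 85.84. Of 45 stem cell genes (median -0.09, percentile 19.2), Socs2 (1.47) and Vwf (1.02) were at least 2-fold higher and the receptor gene Tek (-1.25) lower. Socs2 was named after its value was seen.

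Granulocyte and lymphoid genes headed the lower genes of the DKO array. The 12 largest were Prg3 (-3.53), Ppbp (-3.39), Epx (-3.27), Rnase12 (-3.27), Dntt (-3.12), Klk1 (-3.01), Srsy (-2.88), Stfa3 (-2.87), Ear6 (-2.50), Tdpoz2 (-2.42), the chromatin gene Hmgn5 (-2.37) and Flt3 (-2.30). Stfa3, Srsy, Ear6 and Tdpoz2 have close copies, and Tdpoz2 differed by -0.92 with the mean of its probe sets. With dim signals raised to the floor, Klk1 differed by -0.02, so no difference was left, Stfa3 by -1.82, Srsy by -2.16 and Rnase12 by -2.19. B cell markers were lower (median -0.64), with 6 of 13 at least 2-fold lower, led by Ly6d (-1.59), Fcrla (-1.54) and Vpreb3 (-1.47). Neutrophil markers had a median of -0.54, with 18 of 19 lower, led by Ly6g (-1.79), Retnlg (-1.24) and Cxcr2 (-1.08). The mast cell and basophil list had a median of -0.59, with 6 of 18 at least 2-fold lower, including the basophil protease Mcpt8 (-1.97). These 3 medians lay below all random lists. T and NK cell markers lay at -0.17 (percentile 0.69), with Gzma at -2.06 and Klrd1 at -0.94, while Cd3d stood at 0.99. Endothelial and stromal markers lay at 0.29 (percentile 99.8), with Vwf higher and Pdgfrb at -1.46. Dendritic cell (-0.08, percentile 16.0), erythroid (0.12, percentile 89.4) and megakaryocyte lists (-0.02, percentile 49.8) stayed inside the band, although Itgax differed by 2.37, Rhag by 1.21, Klf1 by -0.93 and Tspo2 by 0.85. Raising dim signals to the floor left differences of 1.60 for Itgax, -0.95 for Fcrla, -0.75 for Pdgfrb and 0.11 for Tspo2, and none for Gzma and Klrd1. With the floor also used for marker lists, chosen after the data were seen, the T and NK cell and the endothelial lists lost their call (percentiles 5.29 and 98.74), and the dendritic cell list (0.695) and the megakaryocyte list (99.65) gained one.

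**Figure D2:**
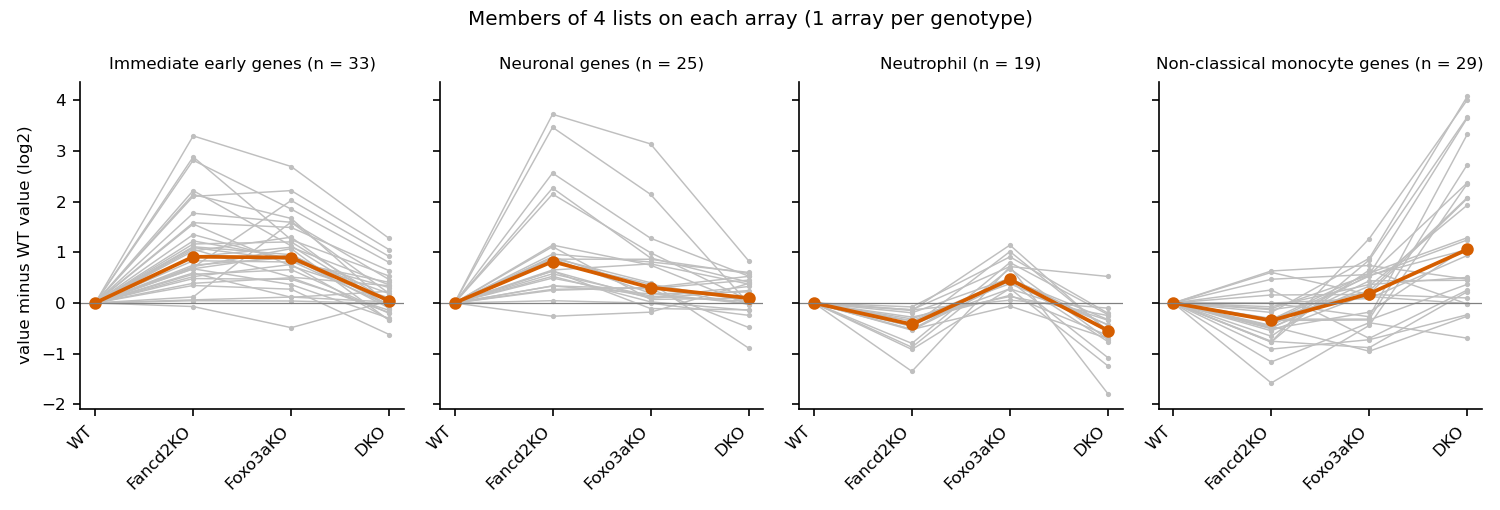
Each grey line joins the values of 1 gene on the 4 arrays, as log2 value minus its WT value (y axis), for 4 lists, and the orange line joins the medians. The neuronal and non-classical monocyte lists were added after the data were seen, neutrophil medians lie at -0.42, 0.46 and -0.54 in the Fancd2KO, Foxo3aKO and DKO arrays, and the non-classical monocyte median lies at 1.06 in the DKO array.

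Loss of Foxo3a on the Fancd2 knockout background was read from DKO minus Fancd2KO. Here 181 genes were at least 2-fold higher and 182 lower. Monocyte genes led the higher ones, with Clec4a3 (4.78), Clec4a1 (4.44), Fcgr4 (4.26), Adgre4 (3.93), Clec4b1 (3.41) and Fcrl5 (3.36). Neural transcripts led the lower ones, with Cdr1 (-4.69), Cpe (-3.53), Snap25 (-3.47), Sparcl1 (-3.05), Pcp4 (-2.89) and the imprinted noncoding RNA Meg3 (-2.80). Clec4b1 differed by 0.77 and Fcrl5 by 1.94 once dim signals were raised to the floor, and the lower differences were -2.18 for Cdr1, -1.92 for Snap25, -1.78 for Cpe, -1.77 for Sparcl1 and -1.56 for Meg3. Immediate early genes had a median of -0.95, below all random lists, with 14 of 33 at least 2-fold lower, among them Nr4a3 (-2.28) and Egr1 (-2.18). FOXO target genes had a median of -0.32, below all random lists, with Cdkn1a (-2.74), S1pr1 (-1.87), Irs2 (-1.23) and Klf6 (-1.14) in front. The TNF and NF-kB list had a median of -0.23 (percentile 0.12) and included Ptgs2 (-2.07) and Ier3 (-1.46). Progenitor genes had a median of 0.13 (percentile 99.4), led by Csf1r (2.42), which is also a monocyte marker, and Cd48 (1.18). Among marker lists, monocyte (0.92) and erythroid (0.49) medians lay above all random lists, the B cell median (-0.57) below all, and the megakaryocyte median (-0.23) at percentile 0.71, or 1.23 with the floor. The lists of T and NK cells, mast cells and basophils, and endothelial cells stood apart only with the floor (percentiles 0.35, 0.18 and 0.55).

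Loss of Fancd2 on the Foxo3a knockout background was read from DKO minus Foxo3aKO, where 142 genes were at least 2-fold higher and 263 lower. The largest higher differences were Fabp4 (5.12), Pparg (3.60), Fcrl5 (3.51), Lipg (3.48), Fcgr4 (3.19) and Cd300e (3.09). The largest lower ones were Stfa3 (-3.77), Cdr1 (-3.69), Klk1 (-3.51), Scrg1 (-3.10), Mcpt8 (-2.82) and Il1r2 (-2.79). On raising dim signals to the floor, Klk1 differed by -0.52, Cdr1 by -1.19 and Stfa3 by -2.72, and the higher differences were 3.71 for Fabp4, 2.32 for Pparg, 2.31 for Lipg and 1.94 for Fcrl5. Immediate early (median -0.88) and TNF and NF-kB genes (-0.23, percentile 0.01) were lower, among them Ptgs2 (-2.60), Ccl2 (-2.33), Egr1 (-1.71) and Fos (-1.41). Interferon response genes were higher, with 34 of 41 above Foxo3aKO and a median of 0.25, above all random lists, led by Lgals3bp (0.90), Usp18 (0.79), Irgm2 (0.75) and Psmb8 (0.70). The FOXO list had a median of -0.15 (percentile 0.54), led by Klf2 (-1.41), and the p53 list a median of -0.14 (percentile 0.58), led by Fas (-1.10). With no floor both calls ended, at percentiles 1.17 and 4.47. Neutrophil (-1.02), T and NK cell (-0.51), B cell (-0.48) and mast cell and basophil (-0.48) marker medians lay below all random lists. Erythroid (0.72) and monocyte (0.57) medians lay above all of them, and the megakaryocyte median (0.29) at percentile 99.9, or 83.56 with the floor.

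The DKO array was also set against the sum of the other differences. Against the additive expectation, 480 genes were at least 2-fold higher and 534 lower, for a quantity that carries the error of 4 arrays and whose SD between probe sets was 0.72. Simulated unchanged arrays gave 463 higher and 462 lower on average and at most 518 and 520, so the higher count lay within their range and the lower count above it. The balance of measured counts turned with quantile normalisation, to 530 and 504, and at a 1.5-fold threshold, to 1631 and 1365. With dim signals raised to the floor, the large lower departures were -5.47 for Pcp4, -4.71 for Nr4a2, -4.69 for Il1r2, -3.37 for Cdr1, -2.70 for Cpe and -2.52 for Snap25. Cdr1 lay in WT and DKO at about the level of unspiked controls (3.03 to 3.14 log2), so its size as measured, -8.39, is not exact. The large higher departures as measured were Adgre4 (4.37), the proteasome gene Psma5 (3.82), Fcrl5 (3.72), Pparg (3.60), Clec4a1 (3.59) and Car1 (3.51), and Psma5 stood at 1.99 with the mean of its probe sets. With dim signals raised to the floor these were 0.44 for Psma5, 1.94 for Fcrl5 and 2.32 for Pparg, so the Psma5 departure was not kept. Of the 79 genes at least 2-fold higher in both Fancd2KO and Foxo3aKO, 22 were so in DKO. Another 36 were less than 0.5 log2 above WT there, a count that includes genes below WT by any amount. Of the 60 genes at least 2-fold lower in both, 38 were so in DKO, with a median of -1.24.

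Comparisons that share the WT array were set beside simulated unchanged arrays. The simulation takes the spread of each gene over the 4 arrays as error, real differences included. It also draws genes independently, so values outside its ranges can arise from genes that vary together. Across 12041 genes, which are not independent replicates, Fancd2KO minus WT and Foxo3aKO minus WT correlated with r = 0.544, and unchanged simulated arrays gave 0.499 on average and 0.535 at most. The covariance exceeded the simulated one by 0.00679. Fancd2KO and DKO gave r = 0.481 (simulated 0.501) and Foxo3aKO and DKO gave 0.467 (simulated 0.498), with covariances -0.00514 and -0.00507 from the simulated ones. Genes at least 2-fold higher in both Fancd2KO and Foxo3aKO numbered 79, against 68.0 simulated and 3.66 for independent lists. Lower genes numbered 60, against 67.7 and 2.11, and 2 genes went in opposite directions, against 11.45 simulated. All 3 counts lay within the range of the simulated sets. Higher genes shared with DKO numbered 36 for Fancd2KO and 46 for Foxo3aKO, where the simulated sets gave 68.3 and 67.6 on average and no fewer than 50 and 52. Shared lower genes, 73 and 59 against 67.5 and 67.5, lay within the simulated range. Since WT has 1 array, it could not be split, and part of any excess may come from that array. Comparisons with no shared array gave r = -0.0626 between both backgrounds for Foxo3a loss, below every simulated set (lowest -0.0517), and -0.0604 for Fancd2 loss, inside the simulated range (lowest -0.0646). Of the counts for single comparisons, 4 lay below every simulated set: 163 lower genes in Fancd2KO, 156 lower genes in Foxo3aKO and 165 higher genes in DKO, each minus WT, and 142 higher genes in DKO minus Foxo3aKO, where the lowest simulated counts were 169, 166, 174 and 163. The 263 lower genes in DKO minus Foxo3aKO lay above the highest, 238. For Foxo3a loss, 6 genes were lower in both backgrounds, where the simulated sets gave 26.4 on average and 14 at least, and for Fancd2 loss 3 were higher in both, where they gave 26.7 and 13. The 19 higher genes for Foxo3a loss and the 22 lower genes for Fancd2 loss lay within the simulated range (means of 26.3 and 25.9).

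**Figure D3:**
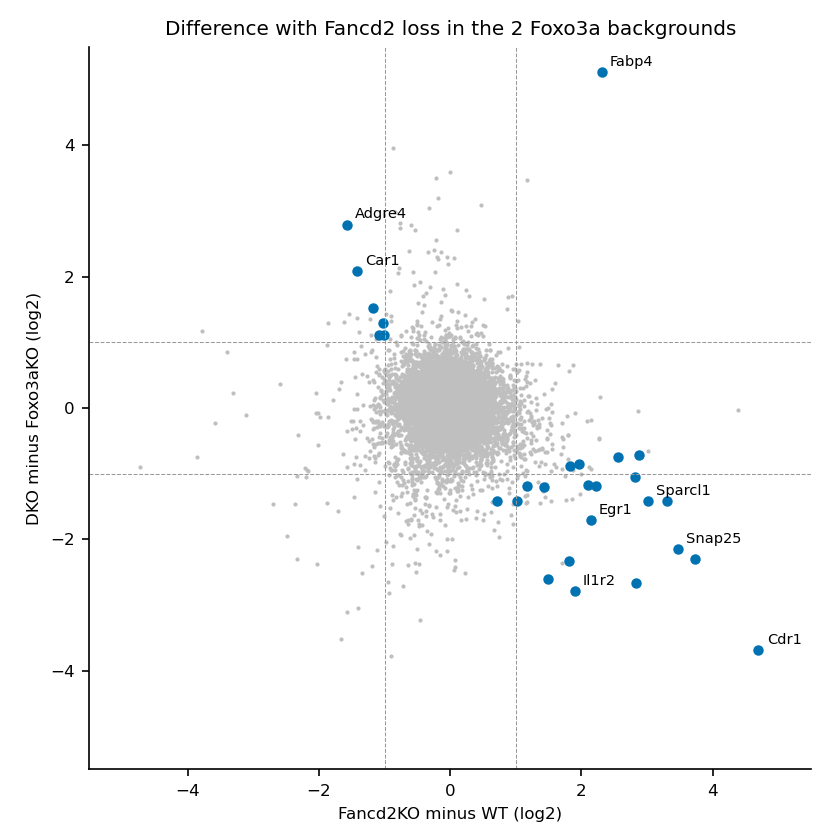
Each point is 1 of 12041 genes, with its log2 difference between Fancd2KO and WT on the x axis and between DKO and Foxo3aKO on the y axis, from 1 array per genotype. Dashed lines mark 2-fold differences, and blue points are the 28 of the genes named by the text's rule that had opposite 2-fold differences for loss of either gene, such as Cdr1 at 4.69 and -3.69, or Car1 at -1.42 and 2.09.

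Most lists of DNA repair, cell division and growth genes had medians inside the band of random lists. Fanconi anaemia genes had medians of 0.07, -0.06 and -0.02 in the Fancd2KO, Foxo3aKO and DKO arrays, at percentiles 83.2, 42.7 and 44.5. For homologous recombination and DNA damage response genes the medians were 0.00, -0.09 and -0.06 (percentiles 60.1, 31.8 and 41.8), and for mitosis genes -0.04, 0.04 and -0.04 (28.6, 94.2 and 65.3). The p53 targets lay at 0.10, 0.00 and 0.08 (95.3, 74.2 and 92.2), antioxidant genes at 0.09, 0.00 and -0.03 (96.7, 79.0 and 59.9), and apoptosis regulators at -0.06, 0.03 and 0.03 (24.5, 82.3 and 79.6). Autophagy and lysosome genes lay at -0.06, -0.03 and -0.12 (23.4, 64.2 and 12.2), mTOR and PI3K-AKT genes at -0.03, -0.11 and -0.07 (40.6, 18.4 and 33.0), and ribosomal protein genes at 0.00, -0.17 and -0.10 (64.0, 1.20 and 14.9). In Foxo3aKO 35 of 40 ribosomal protein genes were lower, and the list stood apart with cyclic loess (percentile 0.88) and with the mean of all probe sets (0.335). DNA replication genes lay inside the band in Foxo3aKO (-0.15, percentile 8.40) and DKO (-0.10, 21.1). Stem cell genes did so in Foxo3aKO (-0.08, 27.3), as did progenitor genes in Foxo3aKO (0.05, 91.0) and DKO (0.06, 97.3). Of 29 lists with a percentile, 12, 9 and 9 stood apart in the Fancd2KO, Foxo3aKO and DKO arrays, where 0.58 would with independent genes.

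Transcripts of both sexes were present on every array. Xist, the RNA of the inactive X chromosome, ran from 10.2 to 11.1 log2. Its differences from WT were -0.88 in Fancd2KO, -0.23 in Foxo3aKO and -0.21 in DKO. The Y-linked gene Eif2s3y ran from 7.92 to 8.81, with differences of 0.63, 0.89 and 0.59 in the Fancd2KO, Foxo3aKO and DKO arrays, and Uty differed by 0.45, 0.62 and 0.52. Every knockout array thus had higher signals of these Y-linked genes and a lower Xist signal than WT. A different mix of sexes in the WT sample was not separable from genotype with 1 array each. Neutrophil transcripts were bright on every array, with S100a8 between 12.9 and 13.1 log2.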

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

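The differences below were singled out because loss of 1 gene went with opposite directions in the wild-type and in the knockout background of the other gene, each at least 2-fold for genes, or outside the band of random lists for lists. Among the genes named by the text's rule this held for 28, among the lists fixed beforehand for 4, and among the lists added after the data were seen for 3. None of these differences was tested, since each rests on 1 array per genotype. The naming rule picks genes with large differences and large departures from the additive expectation, so it favours genes of this kind. A gene flagged for loss of either gene has the same departure in both cases, so its flags are not separate results. Over all genes, 53 had opposite 2-fold differences for Foxo3a loss and 53 for Fancd2 loss, where simulated unchanged arrays gave 52.9 for each. Genes with the same direction in both backgrounds numbered 19 higher and 6 lower for Foxo3a loss, and 3 higher and 22 lower for Fancd2 loss, where the simulation gave 26.3, 26.4, 26.7 and 25.9 on average. Of these 4 counts, the 6 and the 3 lay below every simulated set. The simulation counts real differences between genotypes as error, so neither number separates them. Each gene value below is the departure of DKO from the additive expectation on the log2 scale. With signals under the floor raised to it, 20 of the 28 genes kept opposite 2-fold differences, and Cpe, Fabp4, Snap25, Sparcl1, Vsnl1, Meg3, Socs3 and Spic did not. Among the explanations weighed below, the tests of normalisation for neural genes, of a lower stem cell share for monocyte genes and of neutrophils for immediate early genes were chosen after the results were seen, as was the astrocyte condition of the brain test and the choice of every added list.

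Neural genes, whose dim signals in WT and DKO make the sizes inexact, formed the first group, with Cdr1 at -8.39, Pcp4 at -6.03, Snap25 at -5.62, Cpe at -5.49, Sparcl1 at -4.43, Vsnl1 at -3.31 and the imprinted RNA Meg3 at -2.62. Stimulus-induced genes formed the next group: Nr4a2 (-4.71), Nr4a1 (-3.87), Egr1 (-3.85), Socs3 (-3.60), Nr4a3 (-3.41), Atf3 (-3.27), Plk2 (-2.82), Skil (-2.71), Fos (-2.44), Klf6 (-2.35) and Klf2 (-2.13). Inflammatory genes did likewise, with Il1r2 at -4.69, Ccl2 at -4.14 and Ptgs2 at -4.08. Departures upward were those of the macrophage genes Adgre4 (4.37), Adgre1 (2.70) and Spic (2.31), of the erythroid gene Car1 (3.51), and of Fabp4 (2.81), Mc5r (2.20) and Apobec3 (2.12). As lists, the median difference in the knockout background minus that in the wild-type background was 1.02 for erythroid markers upon Foxo3a loss and 1.17 upon Fancd2 loss. It was -1.84 and -1.79 for immediate early genes, -0.48 and -0.40 for TNF and NF-kB genes, and 0.47 for interferon response genes under loss of Fancd2. Among the added lists it was -0.97 and -1.06 for neuronal genes, -1.20 and -1.25 for rapid response genes, and 1.23 for non-classical monocyte genes under loss of Fancd2. The percentiles behind these lists treat genes as unrelated.

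The neural genes of the Fancd2KO array could come from admixed RNA. RNA of neuronal or neuroendocrine cells had the values it needs. The 21 neuronal genes outside those that prompted the list had a median of 0.63, above all random lists (percentile 100), as had the 15 past the floor. Nrgn was the only neuronal gene on another list, that of megakaryocytes. That list was fixed beforehand, so not every neuronal gene was unseen. The neuronal genes with the brightest signals there, Basp1, Pcp4 and Atp1b1 at 8.76, 8.67 and 8.66 log2, differed from WT by 0.58, 3.72 and 0.89, and the lineage and c-Kit gates should remove such cells but not free RNA. Brain tissue stayed open, with the myelin list at percentile 99.96 and the astrocyte list at 96.28, or 97.4 and 81.7 past the floor. No admixture test was set for Foxo3aKO. There the neuronal, myelin and astrocyte lists past the floor lay at percentiles 99.65, 99.76 and 62.14, so high neuronal and myelin values were not particular to Fancd2KO. Under quantile normalisation and cyclic loess the neuronal list stayed at percentile 100. The smallest difference of Snap25, Pcp4 and Cdr1 was 3.43. The arrays as deposited already lay within 0.0889 log2 of their common mean at every rank, so these methods could hardly change such differences. The pattern did not depend on the choice among them, but the normalisation before deposit was not tested. An effect of genotype was not separable from admixed RNA with 1 array.

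The monocyte genes of the DKO array may reflect non-classical monocytes within the sort. The 21 non-classical genes outside those that prompted the list had a median of 0.47, above all random lists (percentile 100). These 21 were not all unseen, because Cx3cr1, Ms4a6c, Itgal and Itgax among them also stand on lists fixed beforehand. Of the genes of that list with bright signals, Clec4a3 stood at 11.2 and Ctss at 10.5 in DKO, higher by 4.01 and 1.24, while Ifitm3, Cybb and Lst1 differed by 0.10, -0.02 and -0.69. The c-Kit and Sca-1 gates should remove these monocytes, and of the list's 29 genes Fcgr4, Cx3cr1, Csf1r and Ms4a6c are also monocyte markers, Itgal an adhesion gene and Itgax a dendritic cell gene. Classical monocyte genes as a list showed no rise, at percentile 21.46, but this does not exclude some share of such cells. A lower stem cell share that lifts all other cells alike would raise B cell markers too, but these lay at -0.64 beside 0.87 for monocyte markers. Both values were known when this test was chosen. Whether the B cell transcripts came from other cells or from the gated cells was not known, so the test does not exclude it. A lower share that lifts other cells unevenly was not excluded. Expression of these genes by double knockout stem cells predicts the same and was not separable with 1 array.

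The immediate early genes of the Fancd2KO and Foxo3aKO arrays could reflect handling. Neutrophils were excluded only as a source common to both arrays, with marker medians of -0.42 and 0.46 in opposite directions. A neutrophil part in the Foxo3aKO array alone, where these markers were higher, was not excluded. Heat shock stayed open: the list of heat shock genes lay at percentile 54.57 in Foxo3aKO, below the level set for it beforehand, and at 99.84 in Fancd2KO. That level was no fair bar, because the list lacks the heat-inducible genes Hspa1a and Hspa1b, which were higher by 1.60 and 2.02 in Foxo3aKO. Handling of the WT and DKO samples apart from the others stayed open, because the added rapid response genes lay at percentile 100 in both arrays, as a genotype effect also predicts.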

How the results depend on the processing

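Replicates could not be left out, since each group had 1 array. No list that stood apart and no named 2-fold difference reversed under any alternative, and of 50 list calls 43 were kept under every alternative chosen before the data were seen. Raising signals to the floor cannot reverse a difference between a pair of arrays. The arrays had nearly the same distribution as deposited, so the normalisations could move single genes little. The lack of reversals in named genes therefore says little. For 281 differences of named genes, 1124 alternative values moved 6 times, each time with the mean of all probe sets: Psma5 to 1.99, Rsph3a to 0.95, Socs3 to 1.75 in Fancd2KO minus WT and -1.36 in DKO minus Fancd2KO, and Tdpoz2 to -0.92 in DKO and -0.80 in Fancd2KO against WT. With signals under the floor raised to it, chosen after the data were seen, 69 of the 281 differences moved, and 176 of 199 named 2-fold differences stayed at least 2-fold. Counts of higher and lower genes are given here as pairs, in the order Fancd2KO, Foxo3aKO and DKO minus WT, DKO minus Fancd2KO, DKO minus Foxo3aKO, and DKO minus the additive expectation. The reported pairs were 202 and 163, 218 and 156, 165 and 207, 181 and 182, 142 and 263, and 480 and 534. A floor at the 75th percentile gave 94 and 75, 129 and 90, 83 and 101, 96 and 97, 69 and 171, and 233 and 282, as fewer genes entered. A threshold of 1.5-fold gave 664 and 757, 705 and 918, 608 and 758, 642 and 735, 702 and 785, and 1631 and 1365. A threshold of 3-fold gave 51 and 36, 59 and 26, 57 and 50, 69 and 46, 46 and 78, and 121 and 196, by construction. Counting only genes that could be named gave 93, 102 and 130 lower genes against WT. Other count alternatives stayed within 1.5 times the reported counts. The balance of higher and lower counts was less stable. It turned at 1.5-fold for Fancd2KO, Foxo3aKO and the additive departure, at 3-fold for DKO minus WT and DKO minus Fancd2KO, with median centring for Foxo3aKO (185 and 211), among genes that could be named for DKO minus WT (134 and 130), and with quantile normalisation for the additive departure (530 and 504) and DKO minus Fancd2KO (182 and 178). For DKO minus Fancd2KO it also turned with no floor (230 and 228) and without marker, immediate early and added-list genes (155 and 136). Without marker, immediate early and added-list genes, chosen after the data were seen, the pairs against WT were 159 and 150, 182 and 148, and 134 and 182. List calls that ended were DNA replication in Fancd2KO (percentile 98.95 with quantile normalisation, 97.41 with the mean of all probe sets), respiratory chain in Fancd2KO (98.69 with quantile normalisation) and glycolysis in Foxo3aKO (93.85 with the mean of all probe sets, 98.44 with no floor). In DKO minus WT, the WNT, Notch and TGF-beta list ended at 98.14 with quantile normalisation, 98.915 with cyclic loess and 98.44 with no floor, and adhesion at 98.39, 98.31 and 85.84 with quantile normalisation, cyclic loess and the mean of all probe sets. In DKO minus Foxo3aKO, the FOXO call ended at 1.165 with no floor and at 1.84 without immediate early genes, and the p53 call at 4.47 with no floor. Calls gained were FOXO in Foxo3aKO at percentile 0 without immediate early genes, stem cell genes in Fancd2KO at 99.33 with the mean of all probe sets, antioxidant genes in Fancd2KO at 99.03 with no floor, and ribosomal proteins in Foxo3aKO at 0.88 with cyclic loess and 0.335 with the mean of all probe sets. Others gained were TNF and NF-kB genes in DKO minus WT, at 99.215 with quantile normalisation, 99.51 with cyclic loess and 99.01 with the mean of all probe sets, and interferon genes in DKO minus Fancd2KO, at 99.21 with cyclic loess and 99.715 with the mean of all probe sets. With the floor used for marker lists too, chosen after the data were seen, calls ended for T and NK cells (5.29) and endothelial cells (98.74) in DKO minus WT and for megakaryocytes in DKO minus Fancd2KO (1.23) and minus Foxo3aKO (83.56). Calls were gained for dendritic cells in Foxo3aKO (99.3), in DKO minus WT (0.695) and in DKO minus Foxo3aKO (99.79), megakaryocytes in DKO minus WT (99.65), and T and NK cells (0.35), mast cells and basophils (0.18) and endothelial cells (0.55) in DKO minus Fancd2KO. With no floor, the correlation of Fancd2 loss in both backgrounds was -0.0382, and 5 genes were 2-fold higher in both. Where the alternative's construction does not show it, the cause was not tested. Genes near the floor of 5.51 log2 lie below the median of the G and C rich background probe sets, 6.06 to 6.70, so their absence from a count says little.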

Other observations

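At least 2-fold lower than WT on all 3 knockout arrays were 38 genes, and 22 were at least 2-fold higher, where simulated unchanged arrays gave 35.2 and 35.8 on average, with 22 and 23 as the lowest. Ppbp, which encodes a platelet chemokine, stood at 8.66 log2 in WT and at 5.55, 5.37 and 5.27 in Fancd2KO, Foxo3aKO and DKO. The lymphoid and progenitor genes Dntt (8.74, 7.44, 6.57 and 5.62) and Flt3 (8.97, 7.34, 7.37 and 6.67) also stood highest in WT, as did the telomerase RNA Terc (7.93, 7.30, 6.24 and 7.06). As all 3 comparisons share the WT array, these genes describe that array as much as the knockouts.

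Genes of the sorting markers were named after their values were seen. Kit stood at 10.7, 10.4, 10.6 and 10.4 log2 in WT, Fancd2KO, Foxo3aKO and DKO, and the stem cell gene Procr at 7.89, 8.03, 7.80 and 8.05. Cd34 was bright in cells labelled CD34-negative, at 10.8, 10.3, 9.67 and 10.4. Slamf1, which encodes CD150, stood at 7.25, 8.36, 7.51 and 7.81, and Cd48 at 8.17, 7.50, 8.13 and 8.68.

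Lists added after the data were seen gave further values. Rapid response genes had medians of 0.77, 0.50 and 0.05 in Fancd2KO, Foxo3aKO and DKO, and among them Bhlhe40 differed by 2.26, 1.70 and 1.25. Classical monocyte genes were higher in Foxo3aKO, where all 16 lay above WT with a median of 0.58 and 5 were at least 2-fold higher, and F13a1 differed by -0.48, 1.17 and -1.21 over the 3 arrays. Non-classical monocyte genes had medians of -0.35 and 0.18 in Fancd2KO and Foxo3aKO. Imprinted genes had medians of 0.14, -0.02 and -0.01, and the maternally or paternally expressed genes Meg3 (1.43, -0.18 and -1.38), Rian (1.45, 0.10 and -1.05) and Peg3 (1.39, 0.09 and -0.73) went from higher in Fancd2KO to lower in DKO. Meg3 lay under the floor in Foxo3aKO and DKO, and its difference between them was 0 with dim signals raised to the floor. Its lower value in DKO thus rests on a dim signal. Astrocyte genes had medians of 0.18, 0.08 and -0.11, myelin genes 0.43, 0.24 and 0.20, and heat shock genes 0.22, -0.02 and -0.11.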
